A study of Mus musculus with 6 samples.

How the data were processed

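RNA was measured in 6 libraries of mouse dental follicle cells, 3 labelled Het and 3 labelled KO for a conditional allele of Pth1r. Per the labels' protocols, follicle cells of mandibular molars were dissociated with enzymes, cells positive for the red fluorescent reporter tdTomato were sorted, RNA was purified with a PicoPure kit, cDNA was amplified with a SMART-Seq low-input kit and libraries were made with a Nextera XT kit. Amplification from few cells without molecular identifiers means that reads are not independent molecules, so floors given for a count of 0 cover counting error only.

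Per the submitters' processing notes, the authors used the mm10 mouse genome with FastQC, TopHat2 2.0.13, Bowtie2 2.2.1, Cufflinks, Cuffdiff, HTSeq and DESeq2. Those notes give no role for each tool, and the annotation and the strand setting of the counting are not given in the sources used here. The main table holds the whole-number counts per gene symbol as the authors deposited them, without normalization, for 17213 genes. A second deposited table holds estimated counts for 23107 gene symbols, of which 5578 are at 0 in all libraries. In it, 1.66% of values differ from a whole number by more than 1e-06, and these estimated counts were rounded before use. Over the genes of both tables, 92.3% of values were equal within 1e-09. A further deposited table holds FPKM values, fragments scaled by gene length and library size as the authors computed them. Deposited tables of the same counts divided by 1 factor per library, or transformed to regularised logarithms, were not used here. Mitochondrially encoded genes and ribosomal protein genes were not analysed here.

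The total count was 63787622, 34019925 and 35751012 in Het replicates 0, 1 and 2, and 66147200, 58378160 and 51804736 in KO replicates 0, 1 and 2. Groups and replicate numbers came from the sample titles. No label says that the libraries came from separate animals, so the p-values measure only the spread between these samples, which may be partly technical. Each titled library was counted as 1 sample. All pairs of libraries had a chi-square per degree of freedom of 91.3 or more, which sets aside only that 1 amplified library was sequenced under more than 1 title and does not tell technical repeats from separate animals. Xist, transcribed from the inactive X chromosome, was at 0.145 CPM in Het replicate 0 and 0.230 CPM in KO replicate 1, against 23.6 to 78.4 CPM elsewhere. This argues against either being a technical repeat of the other libraries of its group, and leaves those others open.

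Counts were analysed in R 4.3.3 with the quasi-likelihood test of edgeR 4.0.16, run with its default settings, TMM scaling and its default filter on low counts, which left 14632 genes. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Levels are CPM, counts scaled to a common library size after TMM, given as mean ± SD. Standard errors of log2 fold changes were derived from the F statistic. A fold against a group at 0 in all its libraries was computed against a floor of 3 counts over the group. Gene positions came from GENCODE M21, which uses the same assembly as mm10, and older symbols were matched through a RefSeq gene table. Of the symbols in the count table, 15459 (89.8%) matched that annotation directly.

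Before the data were examined, 29 gene lists were fixed, and 28 of them had at least 3 members among the genes tested. The lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the 28 lists. The named genes were also fixed by a rule. Pth1r and Pthlh are always named. Genes past the threshold with a mean log2 CPM of at least 2 and no overlap between groups were to be named, up to 10 per direction by log2 fold change. As fewer passed, the 10 genes per direction with the smallest unadjusted p are given as values that did not pass, skipping predicted genes without a name. Up to 2 members of each list with the smallest p are given in the same way.

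Alternatives fixed before the data were examined were RLE size factors, no filter and a stricter filter, DESeq2 1.42.0, limma-voom with quality weights, the estimated counts, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1) with and without a minimum FPKM of 1 in 3 libraries, the replicate number as a block, each library left out, a minimum fold of 1.5, a threshold of 0.1, camera with an estimated correlation, and fry. On this scale a fold change of FPKM understates the change of low genes. Chosen after seeing the data were edgeR's newer quasi-likelihood method, a covariate for the share of Y-linked transcripts, thinning of all libraries to the smallest total, DESeq2 without Het replicate 2 and DESeq2 with the replicate number as a block.

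The scripts were tested on simulated data for this comparison, with negative binomial counts drawn from the mean expression, trended dispersion and library sizes of these data, and with the changed genes taken from those with a mean log2 CPM of at least 2. Over 14364 genes, edgeR recovered 26% of 50 genes changed by 2-fold, 88% by 4-fold, 96% by 8-fold and 94% by 16-fold, and called 6 of 14164 unchanged genes. Over 14632 genes, DESeq2 recovered 36%, 92%, 100% and 98% in the same order, and called 31 of 14432 unchanged genes. Every simulated gene had exactly the trended dispersion at its mean, and no simulated library stood apart. These shares may therefore overstate recovery in the real data.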

Results

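Cells of the dental follicle, the connective tissue sac around the unerupted tooth that gives rise to cementum, periodontal ligament and alveolar bone, were sorted at postnatal day 8 from mouse mandibular molars. The sorted cells carried a tdTomato reporter for cells expressing PTHrP, the secreted peptide encoded by Pthlh. Libraries of 3 samples labelled Het and 3 labelled KO for Pth1r, the receptor of PTH and PTHrP, held between 34019925 and 66147200 counts. The comparison asks how the transcriptome of these cells differs when the receptor is conditionally deleted. The labels give different days for the tamoxifen pulse that starts the deletion, day 3 in the series text and day 8 in the sample descriptions. Het replicate 2 stood apart from the other libraries. Thinned to the smallest total, it had 14653 genes detected against 15175 to 15914 in the other 5 libraries, and the first principal component, with 38.6% of the variance, separated it from them. Xist, the transcript of the inactive X chromosome, was at 0.145 CPM in Het replicate 0 and 0.230 CPM in KO replicate 1, against 23.6 to 78.4 CPM in the other 4 libraries. Transcripts of 4 Y-linked genes summed to 124 and 170 CPM in Het replicate 0 and KO replicate 1, and to 55.1 to 98.8 CPM in the other 4 libraries. Those 4 libraries thus held RNA of both sexes, and the sex makeup differed between libraries within both groups.

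The targeted gene itself went against the labels. Pth1r (chromosome 9, 110722085 to 110747145 on the minus strand, mm10) was at 371, 286 and 346 CPM in the libraries labelled Het and at 961, 608 and 472 CPM in those labelled KO. The means were 334 ± 43.9 and 680 ± 253 CPM (SD, n = 3 each). The log2 fold change was 1.02 with a standard error of 0.28, and edgeR's quasi-likelihood test gave an adjusted p of 0.740. An exact two-sided permutation test of log2 CPM gave p = 0.1, the smallest that 3 against 3 libraries can give. In DESeq2 the adjusted p was 0.0564. It was 0.0232 in DESeq2 without Het replicate 2 and 0.00416 with the replicate number as a block, both chosen after seeing the data. Counts over the whole gene do not resolve which exons the reads cover, so they do not show whether the deleted part was transcribed. All directions below are therefore those of the libraries labelled KO against the libraries labelled Het. Pthlh (chromosome 6, 147252101 to 147264183), the gene of the ligand, was at 289 ± 47.4 CPM in the libraries labelled Het and 317 ± 28.5 CPM in those labelled KO (SD, n = 3), a log2 difference of 0.13 that lay within the spread between replicates.

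Cd200, an immunoregulatory membrane glycoprotein, was at 259 ± 20.6 CPM in the libraries labelled KO and 83.2 ± 1.04 CPM in those labelled Het (SD, n = 3), a log2 fold change of 1.64 with a standard error of 0.17. Col13a1, a transmembrane collagen, was at 35.6 ± 18.9 CPM in the libraries labelled KO, with a log2 fold change of 3.15. Tnfrsf11b, which encodes osteoprotegerin, the decoy receptor that restrains osteoclast formation, was at 69.5 ± 7.11 against 30.5 ± 5.99 CPM. On the lower side were Glt8d2 at 25.0 ± 1.62 against 49.1 ± 3.61 CPM, the VIP receptor Vipr2 at 4.76 ± 0.599 against 16.3 ± 6.02 CPM, and Tgfbi, a matrix protein induced by TGF-beta, at 163 ± 31.2 against 323 ± 76.9 CPM. With edgeR's quasi-likelihood test 0 of 14632 genes passed an adjusted p of 0.05, and the smallest adjusted p was 0.0796, for Cd200. An unadjusted p under 0.05 was found for 628 genes, 378 higher and 250 lower in the libraries labelled KO. That is fewer than the share of 0.05 of the 14632 genes that tests give on average without any true difference. Cd200 alone passed in limma-voom with quality weights (adjusted p = 0.00797), under the stricter filter (0.0280) and in edgeR's newer quasi-likelihood method (0.0302), the last chosen after seeing the data.

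DESeq2 called 87 genes, 66 higher and 21 lower in the libraries labelled KO. Of these, 46 had a mean log2 CPM of at least 2, 18 were at 0 in all 3 libraries of a group and 3 had counts in 1 library only. Without Het replicate 2 DESeq2 called 175 genes, 77 of them among the 87, and with the replicate number as a block it called 185, 68 of them among the 87; both were chosen after seeing the data. The groups did not overlap for 10.7% of genes, where chance gives 10%. Leaving out Het replicate 0, edgeR called 1 gene, Elane, a granule protease of neutrophil precursors, as lower.

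The other genes named by rank, none of which passed in edgeR, were as follows. Higher in the libraries labelled KO were Arhgef26 (40.8 ± 6.13 against 11.6 ± 2.21 CPM), the guanylate cyclase subunit Gucy1a3 (101 ± 15.1 against 32.1 ± 9.92 CPM), the growth factor gene Pdgfa (141 ± 23.3 against 65.4 ± 4.58 CPM), Ramp1, an accessory protein of the CGRP receptor (76.0 ± 26.8 against 20.7 ± 7.86 CPM), and the sphingomyelin synthase gene Sgms2 (226 ± 46.0 against 108 ± 9.26 CPM). Phactr1 had 85, 246 and 143 counts against 4, 1 and 1. Lipc was at 0 in all 3 libraries labelled Het and at 2.46 ± 1.83 CPM in those labelled KO, at least 110-fold higher against a floor of 3 counts over the group. Lower were the small leucine-rich proteoglycan gene Aspn (52.9 ± 12.1 against 122 ± 34.9 CPM), the smooth muscle cytoskeletal gene Tagln (87.5 ± 6.95 against 168 ± 36.8 CPM), Stbd1 (37.2 ± 6.75 against 76.2 ± 17.2 CPM), the potassium channel subunit gene Kcne4 (14.4 ± 4.64 against 57.7 ± 41.6 CPM) and the imprinted transcript H19 (74.0 ± 5.49 against 144 ± 42.9 CPM). The Kcne4 log2 fold change of -2.00 became -1.22 without Het replicate 2, the library that stood apart. Pcdha12 had 1, 0 and 0 counts in the libraries labelled KO against 41, 52 and 89, and Cd5 averaged 0.00547 against 0.814 CPM. The value of Pcdha12 is uncertain, because its counts were 64.0% of its estimated counts and the genes of its cluster share exons. All of these except Cd5 passed in DESeq2.

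**Figure D1:**
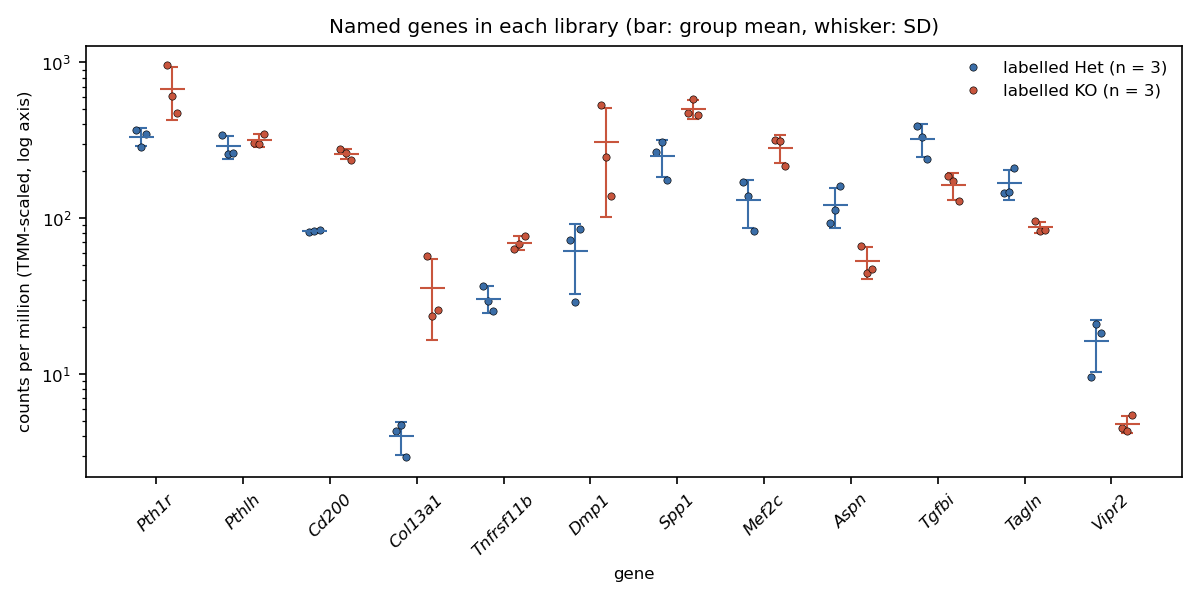
Expression of 12 named genes in each library, in TMM-scaled CPM on a log axis, with points for libraries (3 labelled Het, 3 labelled KO), bars for group means and whiskers for the SD. Pth1r lies at 472 to 961 CPM in the libraries labelled KO and at 286 to 371 CPM in those labelled Het, and none of the genes shown passed an adjusted p of 0.05 in edgeR.

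Genes of mineralising cells were higher as a set in the libraries labelled KO. Of 22 tested members of the osteoblast and mineralisation list, 17 had higher and 5 lower fitted values, with a median log2 fold change of 0.35. The bone matrix gene Spp1 was at 503 ± 67.2 against 252 ± 68.0 CPM, and Ifitm5, a membrane protein of osteoblasts, at 212 ± 112 against 80.5 ± 62.7 CPM (SD, n = 3 each). The Ifitm5 log2 fold change of 1.39 became 2.23 without Het replicate 0. The list passed camera with an adjusted p of 0.0119 (adjusted p = 0.632 with an estimated correlation), and 0 members passed edgeR over all genes or adjusted over the list alone. The list no longer passed without Het replicate 1 (0.229), Het replicate 2 (0.0651) or KO replicate 0 (0.128). Among 6 osteocyte and cementocyte genes, Dmp1, a matrix phosphoprotein of osteocytes and odontoblasts, was at 308 ± 206 against 62.1 ± 29.3 CPM and the transcription factor Mef2c at 283 ± 57.4 against 132 ± 44.9 CPM. The Dmp1 log2 fold change of 2.31 became 1.67 without KO replicate 0. Both passed edgeR adjusted over the list alone, and the list did not pass camera (adjusted p = 0.184). Here and below, an adjustment over the list alone makes no correction for the number of lists tested. Of 6 cementum-associated genes, 4 (Spp1, Sparcl1, Ibsp and Rerg) were higher and passed adjusted over the list alone. Sparcl1 was at 325 ± 20.3 against 224 ± 49.4 CPM, and the Ibsp values overlapped between the groups. In edgeR over all genes these 4 did not pass (adjusted p = 0.648 for Spp1 and 0.976 for Sparcl1, Ibsp and Rerg). The other 2 had lower fitted values and did not pass, Ptpla at 57.2 ± 8.07 against 76.3 ± 6.75 CPM and Wif1 at 2905 ± 308 against 3001 ± 919 CPM. The list did not pass camera (adjusted p = 0.0618; adjusted p = 0.632 with an estimated correlation) or fry's directional test (adjusted p = 0.194). On the same values fry's mixed test, which asks whether members change in either direction, passed with an adjusted p of 0.00110. Camera passed the list in 4 of 21 other fits, under the stricter filter (0.0192), with FPKM pseudocounts of 1 (0.0129) and 0.1 (0.0288) and without Het replicate 2 (0.0402). Spp1 and Ibsp belong to both the osteoblast and the cementum list. Adjusted over the osteoblast list, the same edgeR tests did not pass (adjusted p = 0.0568 for Spp1 and 0.203 for Ibsp).

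Genes of the periodontal ligament, the fibrous tissue that anchors the tooth, were lower as a set. Of 15 members, 11 had lower and 4 higher fitted values in the libraries labelled KO, with a median log2 fold change of -0.38. Aspn was the only member to pass adjusted over the list alone, and the tenascin gene Tnn was at 28.7 ± 8.22 against 54.2 ± 11.1 CPM. The list passed camera with an adjusted p of 0.0119 (adjusted p = 0.632 with an estimated correlation), and it no longer passed without Het replicate 0 (0.0956) or KO replicate 2 (0.0889). The pericyte and smooth muscle list had 8 of 10 members lower (camera adjusted p = 0.0526), with Tagln passing adjusted over the list alone and the actin gene Acta2 at 527 ± 40.9 against 746 ± 58.7 CPM. The IGF axis had 9 of 10 members lower (camera adjusted p = 0.0618), among them Igfbp6 at 24.4 ± 5.94 against 44.1 ± 2.86 CPM and Igfbp5 at 3242 ± 801 against 5225 ± 1614 CPM. In the list of follicle and mesenchymal progenitor genes (camera adjusted p = 0.299995), Twist1 was at 172 ± 25.5 against 232 ± 32.9 CPM and Msx1 at 166 ± 36.1 against 228 ± 34.1 CPM.

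The other lists past the threshold hold immediate early genes, which cell dissociation also induces, and cell cycle genes. In the former, 15 of 19 members had higher fitted values, with a median log2 fold change of 0.45, Jun at 2370 ± 447 against 1542 ± 209 CPM and Socs3 at 773 ± 246 against 397 ± 165 CPM. Its camera adjusted p was 0.00224 (adjusted p = 0.632 with an estimated correlation), and it no longer passed without Het replicate 1 (0.518) or KO replicate 2 (0.0719). In the latter, 21 of 25 members had higher fitted values, with a median of 0.33, and the replication licensing genes Mcm3 and Mcm5 were at 133 ± 47.1 against 81.2 ± 10.7 CPM and 135 ± 33.5 against 86.1 ± 19.5 CPM. Its camera adjusted p was 0.00389 (adjusted p = 0.632 with an estimated correlation), and it no longer passed without Het replicate 1 (0.274), KO replicate 0 (0.128) or KO replicate 2 (0.0889). In both lists 0 members passed over all genes or adjusted over the list alone.

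Genes known to respond to PTH or cAMP did not move together. Of 17 members, 9 had higher and 8 lower fitted values (camera adjusted p = 0.800). The cAMP phosphodiesterase genes Pde4b and Pde4d were at 22.7 ± 2.65 against 44.7 ± 10.8 CPM and at 9.73 ± 1.43 against 16.6 ± 1.63 CPM. In the osteoclast regulation list (0.425), Tnfrsf11b passed adjusted over the list alone and Sfrp1 was at 513 ± 63.4 against 678 ± 159 CPM. In the Wnt list (0.452), Wnt11 was at 96.0 ± 12.6 against 148 ± 5.85 CPM and Ror2 at 114 ± 20.1 against 74.9 ± 10.4 CPM. The lists for BMP and TGF-beta, Hedgehog, Notch, matrix proteases, chondrocytes, and hypoxia and glycolysis each had a camera adjusted p of 0.753. In them Chrdl1 was at 7.02 ± 0.765 against 1.55 ± 1.91 CPM, Gas1 at 751 ± 233 against 441 ± 253 CPM, Jag2 at 41.1 ± 18.2 against 23.7 ± 9.54 CPM, Heyl at 30.3 ± 5.76 against 21.4 ± 4.89 CPM, Mmp9 at 39.5 ± 4.42 against 27.4 ± 4.04 CPM and Adamts4 at 71.8 ± 18.9 against 54.9 ± 2.77 CPM. The Chrdl1 log2 fold change of 2.18 became 3.86 without Het replicate 1. In the hypoxia and glycolysis list Ndrg1 was at 73.4 ± 12.3 against 43.9 ± 20.7 CPM and Pfkl at 187 ± 26.1 against 251 ± 114 CPM. The cartilage collagen gene Col2a1, at 23.4 ± 11.1 against 6.48 ± 2.40 CPM, passed adjusted over the chondrocyte list alone, while Col9a1 went the other way, at 0.685 ± 0.577 against 3.87 ± 3.46 CPM. The Col9a1 log2 fold change of -2.49 became -1.45 without Het replicate 0. In the fibrillar collagen list (0.676), Col11a2, at 129 ± 82.0 against 18.7 ± 17.2 CPM, passed adjusted over the list alone, and Lox was at 257 ± 73.1 against 155 ± 46.5 CPM. The Col11a2 log2 fold change of 2.78 became 3.86 without Het replicate 0 and 2.15 without KO replicate 0. The interferon list gave 0.353, with Ifit3 at 1.06 ± 0.571 against 4.48 ± 1.32 CPM. The unfolded protein list gave 0.925, with Herpud1 at 138 ± 25.4 against 200 ± 49.7 CPM, Sdf2l1 at 53.0 ± 15.2 against 65.0 ± 17.8 CPM and a test direction opposite in sign to its median of 0.07.

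**Figure D2:**
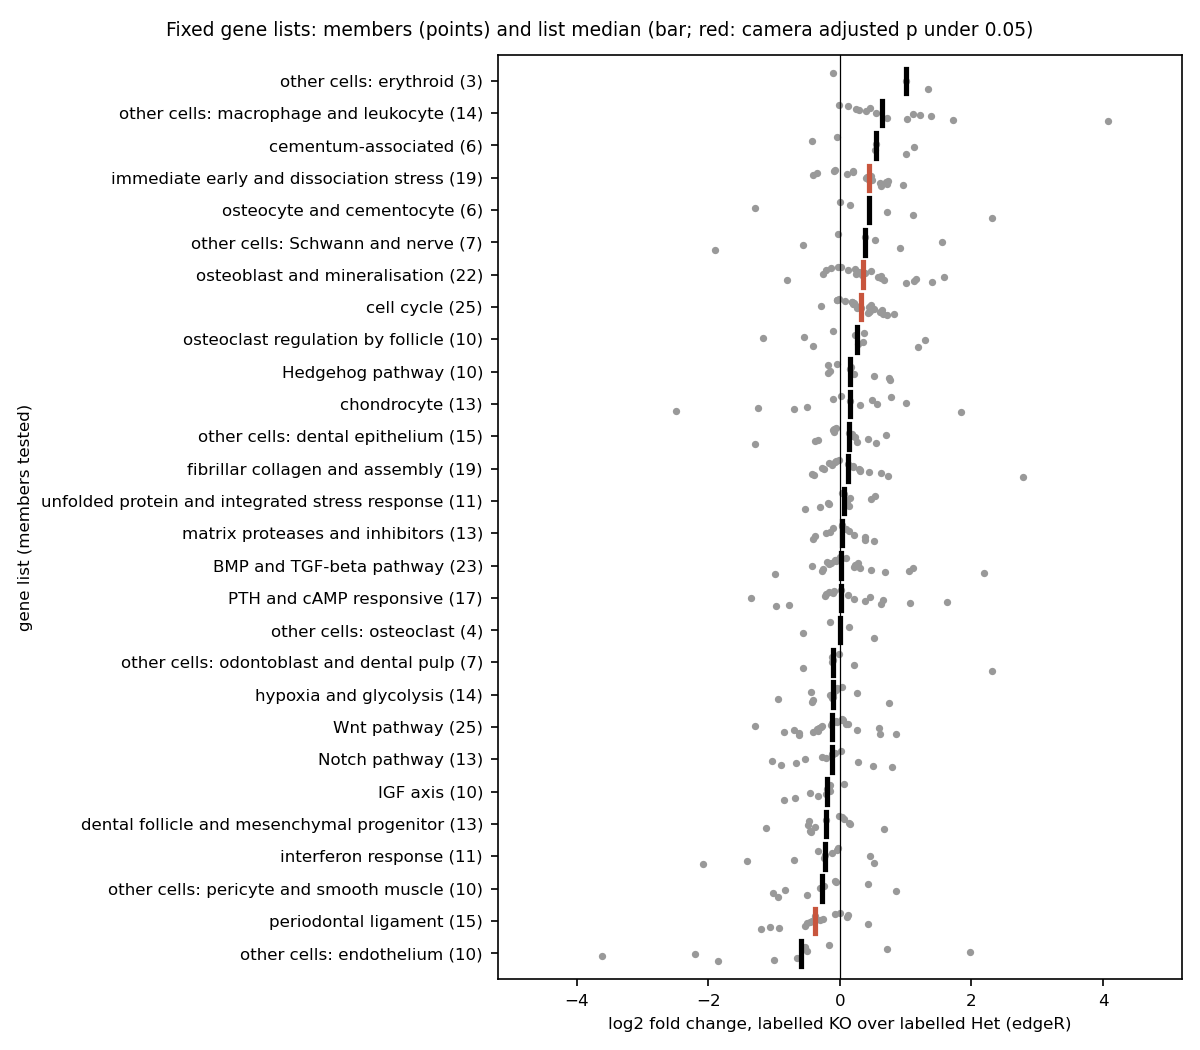
Log2 fold change in edgeR of the libraries labelled KO over those labelled Het (horizontal axis) for 28 gene lists (vertical axis, tested members in brackets), with grey points for members and a bar for each list's median, red where camera's adjusted p was under 0.05. The periodontal ligament list lies at -0.38, and the immediate early, osteoblast and cell cycle lists lie at 0.45, 0.35 and 0.33.

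Markers of other cell types were also measured, because a sort can hold other cells. The macrophage and leukocyte list had 13 of 14 members higher (camera adjusted p = 0.0938; adjusted p = 0.868 with an estimated correlation), with values that differed between libraries of both groups. Its mean log2 CPM was -1.24, 1.998 and 1.62 in Het replicates 0, 1 and 2 and 0.30, 2.45 and 3.12 in KO replicates 0, 1 and 2. Adgre1, under its older symbol Emr1, was at 1.55 ± 1.44 against 0.0928 ± 0.161 CPM and C1qb at 4.93 ± 4.12 against 1.499 ± 1.52 CPM. The C1qb log2 fold change of 1.72 became 2.80 without Het replicate 2 and 1.08 without KO replicate 1, and that of Emr1, 4.07, became 3.19 without KO replicate 1 and 3.45 without Het replicate 0, while without Het replicate 1 no counts were left in the libraries labelled Het. The endothelial list had 8 of 10 members lower (0.124), with Pecam1 at 1.07 ± 0.595 against 3.88 ± 2.57 CPM and Kdr at 3.60 ± 1.06 against 7.21 ± 1.79 CPM. The Pecam1 log2 fold change of -1.85 became -1.19 without Het replicate 2. The erythroid list gave 0.353, and Alas2, at 24.4 ± 11.1 against 9.61 ± 2.92 CPM, passed adjusted over the list alone, with Slc4a1 at 5.68 ± 4.35 against 2.84 ± 2.91 CPM. The Slc4a1 log2 fold change of 1.00466 became 2.08 without Het replicate 2 and 0.41 without KO replicate 2. Dental epithelium, osteoclast, and Schwann and nerve lists each gave 0.753, and odontoblast and dental pulp 0.887, in which Dmp1 passed adjusted over the list alone and Smoc2 was at 339 ± 26.8 against 500 ± 130 CPM. In the osteoclast list Acp5 was at 27.0 ± 3.52 against 39.7 ± 21.8 CPM, and in the Schwann and nerve list Mbp was at 12.8 ± 4.51 against 6.76 ± 3.85 CPM. Enamel matrix genes of the epithelium were abundant in both groups, with Ambn at 4323 ± 2013 CPM in the libraries labelled KO and 2943 ± 1275 CPM in those labelled Het, and Odam was at 157 ± 30.6 against 385 ± 308 CPM. The Odam log2 fold change of -1.30 became -0.66 without Het replicate 2. The skeletal muscle list had too few tested members for a test, and its Mylpf was at 1.31 ± 0.329 against 3.81 ± 2.08 CPM and Tnnt3 at 0.840 ± 0.0715 against 1.16 ± 0.965 CPM.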

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

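Chosen after seeing the data were the newer quasi-likelihood method, the Y-linked covariate, thinning, and DESeq2 without Het replicate 2 or with a block. The count of genes past the threshold, 0 in edgeR, stayed 0 with RLE factors, no filter, estimated counts, a minimum fold of 1.5, the Y-linked covariate and thinning. It was 1, higher in the libraries labelled KO, with the stricter filter, limma-voom, the newer method, each of the 3 FPKM settings and a threshold of 0.1. This gene was Cd200, except in the FPKM settings, which called Mir3061, named after its values were seen. DESeq2 called 87 (66 higher, 21 lower), without Het replicate 2 it called 175 (137 higher, 38 lower), and with the block 185 (159 higher, 26 lower). Leaving out 1 library in edgeR gave 0 to 1 genes in all, 0 to 1 lower and 0 higher, and the 1 gene, without Het replicate 0, was Elane. The cause of these differences was not tested.

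Pth1r kept its direction in every alternative, with a log2 fold change between 0.71 without KO replicate 0 and 1.23 without KO replicate 2, and adjusted p between 0.00416 and 0.99996. It passed at 1.05 in DESeq2 without Het replicate 2 and at 0.97 in DESeq2 with the block. Over 73 named genes and 1571 values under alternatives, 1484 kept direction and side of the threshold, 82 now passed and 5 reversed. The Tnnt3 log2 fold change reversed to 0.32 in limma-voom, to 0.48 in DESeq2 without Het replicate 2 and to 0.48 without Het replicate 2 in edgeR, where leaving out 1 library gave -0.78 (without Het replicate 0) to 0.48. The Pfkl log2 fold change reversed to 0.0155 in DESeq2 without Het replicate 2 and to 0.0170139 without it in edgeR, where leaving out 1 library gave -0.60 (without Het replicate 1) to that value. The cause was not tested.

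The count of gene lists past the threshold, 4, was 9 with the stricter filter, 10 and 7 with FPKM pseudocounts of 1 and 0.1, 8 at a threshold of 0.1, 0 with an estimated correlation, 0 with fry and 1 with fry's mixed test. Leaving out 1 library gave 1 (without KO replicate 2) to 7 (without Het replicate 2 or KO replicate 1), and 2 without Het replicate 1. The 4 lists kept their directions in all 21 other fits.

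The labels do not say whether equal replicate numbers mark paired samples, so the main fit did not pair them. The deviations of same-numbered libraries correlated across genes at 0.169, 0.0746 and 0.0694, although every library correlated best with its own number, a hint from the data and not the design. With the replicate number as a block, edgeR called 0 genes (908 at an unadjusted p under 0.05), Pth1r had a log2 fold change of 0.97 and 5 lists passed. With 3 libraries per group, edgeR recovered 26% of simulated 2-fold changes, so changes of that size were often not detectable. The simulation lacked spread in dispersion between genes of equal mean, so its higher recovery of larger folds need not hold here. In the data, Col13a1 (log2 fold change 3.15, adjusted p = 0.267) and Col11a2 (2.78, adjusted p = 0.648) did not pass edgeR.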

Other observations

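All tests below were chosen after the results of the fixed analysis were seen. The tests of Pth1r were written down after their own values were seen, and the other tests, with the macrophage, granulocyte and imprinted gene lists, before their own values were seen. The genes named in the next paragraph, and the single leukocyte genes below, were chosen after their values were seen.

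Some single genes outside the fixed lists passed in DESeq2 and not in edgeR, and no pathway was tested on them. Ptgis, which encodes prostacyclin synthase, was at 44.8 ± 20.7 CPM in the libraries labelled KO against 13.1 ± 2.71 CPM in those labelled Het (DESeq2 adjusted p = 0.00109, edgeR adjusted p = 0.634). Ptgir, the prostacyclin receptor, was at 1.07, 2.35 and 0.418 CPM against 0 in all 3 libraries labelled Het (DESeq2 adjusted p = 0.00459, edgeR 0.634). Cpe, a carboxypeptidase that processes peptide hormones, was at 1335 ± 194 against 718 ± 56.1 CPM (DESeq2 adjusted p = 9.36e-04, edgeR 0.634), and Loxl4, a lysyl oxidase of collagen crosslinking, at 56.3 ± 25.9 against 11.4 ± 7.20 CPM (DESeq2 adjusted p = 0.00137, edgeR 0.634).

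Pth1r was higher in the libraries labelled KO. Library size or scaling is argued against as the cause, since the lowest log2 fold change over 10 other scalings, filters and tables was 0.97. The filters and the estimated counts could hardly move it. Pth1r had at least 10258 counts in each library, and its counts were 100% of its estimated counts. The argument thus rests on the other scalings, such as RLE factors at 1.02 and FPKM with a pseudocount of 1 at 0.97. An exchange of 1 library per group stays open. With each of the 9 possible exchanges undone, the log2 difference of geometric means was above 0 in 7 and lowest at -0.20, for KO replicate 0 with Het replicate 1. In 0 of the 9 did all KO values lie below all Het values. That count was fixed in advance, because the groups did not overlap, and decides nothing. A candidate explanation for Pth1r not being lower is that a transcript lacking the deleted exons is still made and counted. By itself that would not account for the higher values. Another candidate is that the labels of the groups are reversed. Neither was tested, as exon-level data were not used here. The list of candidates is not complete. A different mix of cells in the sort, named below for the osteoblast list, was not tested for Pth1r either.

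Leukocyte genes differed between libraries although cells were sorted for tdTomato, a gate that would remove unlabelled leukocytes. Macrophage RNA in KO replicates 1 and 2 remained a candidate. The mean log2 CPM of 12 further macrophage markers was 1.37 and 1.65 there, 1.15 above the highest of the other 4 libraries. The mean of the granulocyte precursor markers was also highest in KO replicate 2, at 3.73, and the test did not separate macrophages from other leukocytes. Single markers were less specific, as Mrc1 (3.68 CPM) and Ms4a7 (2.05 CPM) were highest in Het replicate 2, Ctss was at 3.62 CPM there against 3.09 CPM in KO replicate 1, and Fcgr3 (5.62 CPM), Cybb (7.54 CPM) and Lyz2 (72.7 CPM) were higher in Het replicate 1 than in KO replicate 1 (3.22, 7.24 and 63.3 CPM). Granulocyte precursor RNA in Het replicates 1 and 2 had a gap of -0.63 in the mean of 7 markers. By the rule written beforehand, this gap went against that explanation. The explanation stays open only on values seen afterwards, because the list mixes genes of later granules, such as Ltf, with Prtn3. Ltf was at 76.3 CPM in KO replicate 2, and Prtn3 at 20.6 CPM in Het replicate 1 and 2.72 CPM or less elsewhere. Outside that list, Mpo was at 228 and 52.4 CPM and Elane at 66.2 and 33.8 CPM in Het replicates 1 and 2, against at most 1.07 and 0.0985 CPM in the other 4 libraries, and a difference due to genotype was not tested.

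The osteoblast list was higher and the periodontal ligament list lower in the libraries labelled KO, with a difference of medians of 0.74. With all libraries thinned to the smallest total it was 0.78 and both lists passed camera. The list members were abundant, with a median log2 CPM of 7.58 in the osteoblast and 7.89 in the ligament list. Thinning leaves the expected CPM of such genes unchanged. It could therefore hardly move the difference, and the test does not decide on depth. The sparse library Het replicate 2 stays narrowly open. The difference of 0.52 without it exceeded the bound written beforehand, 0.369, by slightly less than its spread of 0.158. That spread is the SD over resampled list members, a measure chosen after the difference was seen. It covers the choice of genes and not the variation between libraries, so it does not settle the question. Without Het replicate 2 the osteoblast list lost its call (camera adjusted p = 0.0651, and 0.0691 in DESeq2), with a median of 0.28 in place of 0.35, while the ligament list kept its call at 0.0204. With an estimated correlation neither list passed (adjusted p = 0.632). Of the 10 splits of the 6 libraries, 1, the real one, gave a difference as large, the highest other being 0.55, and 10 splits are too few for a share under 0.05. A different mix of cells in the sort and a difference due to genotype may both account for it and were not tested.

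The same 10 splits, too few for a share under 0.05, were applied to the counts. In edgeR the real split gave 0 genes (628 at an unadjusted p under 0.05), which every split reaches whatever the data, so the 10 of 10 splits and the highest other of 1 decide nothing. In DESeq2 the real split gave 87 and the highest other 37, with 1 of 10 as large. In camera the real split gave 4 lists and the highest other 6, with 4 of 10 as large. Because H19 was lower in the libraries labelled KO, 9 imprinted growth genes were tested as a set, with 6 lower and 3 higher, a median log2 fold change of -0.15 and a camera p of 0.424.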
